A study of Homo sapiens with 4 samples.

How the data were processed

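The series holds 4 poly-A RNA libraries of U87MG glioblastoma spheres, 2 untreated and 2 treated with abemaciclib, collected at day 14. Per the labels' protocols, total RNA was isolated with Trizol and the libraries were made with a stranded mRNA kit (TruSeq Stranded mRNA). The deposited files hold 1 library each. Per the file headers, their columns are a gene identifier, a gene name and an expected count, an estimate of the reads from that gene that need not be whole. The submitters' processing notes name STAR 2.7.2b, RSEM 1.3.1 and the genome build GRCh38, without their order or settings. The annotation release, the read trimming and the strand setting of the counting were not given in the sources used here. An expected count divides reads that match several genes among them, so genes of families and genes with pseudogenes carry an uncertainty that replicate spread does not show. The deposited values were not scaled for depth or length.

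Each file lists the same 60617 genes, all with a name. Between 6.13% and 6.70% of the values per library were not whole, and they were rounded to whole numbers before the tests. That share is over all listed genes, undetected ones included, and 23223 to 24422 genes per library had at least 1 count. Totals per library were 27485206 and 33418075 (untreated) and 23684260 and 33226884 (abemaciclib), and 3 counts in a library correspond to 0.0898 to 0.127 CPM (counts scaled to a common library total). Groups and replicate numbers came from the sample titles. Coordinates, gene types, GC content and transcript lengths came from GENCODE release 29 on GRCh38, the same build as the processing notes name, matched by Ensembl identifier (58444 of the identifiers, 96.4%). The other identifiers had no match in that release, so the counting used a different annotation. The gene types and overlaps given here may therefore differ from those in the counting.

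Genes were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1) by the quasi-likelihood F test, with filterByExpr on the groups, TMM scaling, robust estimation and the model of group alone, which leaves 2 residual degrees of freedom per gene before the spread is shared across genes. The test was two-sided, with Benjamini-Hochberg adjustment over the 17207 genes that passed the filter, which hold at least 99.9% of the counts of each library. CPM values are TMM-scaled. The standard error of a log2 fold change is its size divided by the square root of F. The common dispersion was 0.000818, a coefficient of variation between replicates of 2.86%. Replicates were compared by a chi-square of their counts over genes with at least 20 counts in the pair. Where a group had 0 counts, the fold is a bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio of scaled counts is given with an exact (Clopper-Pearson) 95% interval. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. In the 6 gene lists that hold any of the 7 genes with 3 counts or fewer in a group, the medians were recomputed with these genes at their bound, and 0 medians moved.

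The 36 gene lists (1363 entries, of which 7 matched no gene name in the files) were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. They cover the cell cycle, stemness, Wnt and other signalling, glioblastoma states, neural differentiation, metabolism, organelles, stress, secreted factors, markers of other cell types and signs of RNA quality. Lists were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 36 lists, then with an estimated correlation, and with fry. Fry's directional test asks whether a list's genes move, on balance, one way, and its mixed test, which called 36 lists, whether they change in either direction. Neither compares a list with other genes. Named genes are the 5 of the series title and the drug's targets, the 10 with the largest positive and the 10 with the largest negative log2 fold change among protein-coding genes past an adjusted p of 0.05 (with a mean of at least 5 CPM in the higher group, groups that do not overlap, and XIST and Y-linked genes left out), and from each list up to 4 members with the smallest p plus the member with the smallest p in the opposite direction. Genes named outside that rule are said to be so, and some genes that the rule selects are not reported here.

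The test was tried on simulated data, with counts drawn for 16784 genes. The draws used each gene's mean over all 4 libraries, the library sizes and the trend of the dispersion on expression, without spread of single genes around it. Of 50 genes changed at each fold, 48% were recovered at 1.25-fold, 76% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and 4.73% of the calls were false. Far fewer genes were changed than in the data, so these shares do not carry over to the real comparison. A simulated list of 40 genes shifted by 0.5 on the log2 scale gave a camera p of 9.14e-57 with the preset and 0.0126 with an estimated correlation, and an unchanged list gave 0.6 and 0.755.

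The alternatives were RLE, upper-quartile and library-size scaling, no filter beyond 1 count, a filter of at least 50 counts in at least 2 libraries, DESeq2 1.42.0, limma-voom, edgeR without robust estimation in its older form, edgeR's exact test, counts not rounded, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were an offset that removes the trend of fold change on GC content and transcript length (loess, span 0.5, fitted on 14302 genes with a mean of at least 1 CPM, with values for 99% of the tested genes), leaving out mitochondrially encoded genes, and a test against a log2 fold change of 1 (glmTreat). Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No file was left out.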

Results

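Messenger RNA was measured in U87MG, an established human glioblastoma line, grown as spheres in a stem cell medium that held EGF and bFGF at 20 ng/ml each, N2 and 2% B27. Spheres kept for 14 days with abemaciclib, a small-molecule inhibitor of the kinases CDK4 and CDK6, were compared with untreated spheres. The dose of the drug and what the untreated spheres received were not given in the sources used here. Each group had 2 poly-A libraries. The untreated libraries held 27485206 (replicate 1) and 33418075 (replicate 2) expected counts, and the abemaciclib libraries 23684260 and 33226884. The replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.56 for the untreated pair and 1.95 for the abemaciclib pair, so each library counted as 1 sample. Nothing in the labels says that they came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical. Mitochondrially encoded genes held 4.27% and 4.66% of the counts in the untreated libraries and 11.8% and 11.7% in the abemaciclib libraries.

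Most measured genes differed between the abemaciclib and the untreated libraries. Of 17207 genes tested, 6542 were higher and 6757 lower after the drug (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), which is 77.3% of them. A change of at least 2-fold was seen in 2378 genes that rose and 2986 that fell, and one of at least 4-fold in 728 and 1265 genes. The libraries of the 2 groups did not overlap in 87.9% of the tested genes. Chance gives 33.3% if all 4 libraries are independent, which the labels do not say. The median log2 fold change of the tested genes was -0.01.

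The 10 protein-coding genes that rose furthest by the fixed rule were led by PSG4, which encodes a pregnancy-specific glycoprotein, at 0.287 ± 0.276 CPM (TMM-scaled counts, mean ± SD, n = 2) untreated and 30.6 ± 1.74 CPM after the drug. ATP6V0D2, a subunit of the proton pump of lysosomes, went from 1.09 ± 0.231 to 62.3 ± 0.873 CPM, a log2 fold change of 5.81 ± 0.10 (SE). MMP12, the macrophage elastase, went from 2.37 ± 0.105 to 90.8 ± 3.85 CPM (5.25 ± 0.08). The secreted guidance factor SEMA3E (5.48 ± 0.27), CCDC198 (5.02 ± 0.24), the ubiquitin ligase subunit ASB2 (4.96 ± 0.23) and the nuclear body protein SP140 (4.77 ± 0.15) followed. The remaining ones were KMO, an enzyme of the kynurenine pathway (4.73 ± 0.26), the calcineurin regulator RCAN2 (4.71 ± 0.15) and TTC39A (4.64 ± 0.18). All 10 had an adjusted p of 1.39e-06 or less in the edgeR test. PSG4 belongs to a family of near-identical genes, among which the authors' counting may have split reads.

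Several of the genes that fell furthest were nearly undetected after the drug. CDKN1C, which encodes the CDK inhibitor p57, fell from 1598 counts over the untreated libraries to 3 counts, a 517-fold ratio of scaled counts (95% counting interval 176.5 to 2509). The proteoglycan gene BGN also fell to 3 counts (396.5-fold, 135.4 to 1925), as did PIK3R6, a regulatory subunit of PI3-kinase gamma (252.9-fold, 86.22 to 1229). C2CD4A fell to 2 counts (263.9-fold, 72.7 to 2185) and the calpain CAPN12 to 1 count (326-fold, 58.11 to 12910). AL163636.3 had 546 counts untreated and 0 after the drug, which makes it at least 177-fold lower against a floor of 3 counts over the group. With more counts left, log2 fold changes were -8.61 ± 0.18 for the interferon-induced IFITM1, -7.98 ± 0.12 for the immediate-early nuclear receptor NR4A1, -7.34 ± 0.28 for AC013271.1 and -6.64 ± 0.15 for YPEL4. NR4A1 went from 88.2 ± 1.78 to 0.325 ± 0.166 CPM (n = 2). The edgeR adjusted p of these 10 genes was 9.47e-17 or less. AL163636.3 overlaps ANG and RNASE4 on the same strand, AC013271.1 overlaps LIMS3 and IFITM1 overlaps IFITM2, so their values are uncertain where the counting could share reads. On the opposite strand CAPN12 overlaps ACTN4, BGN overlaps HAUS7, YPEL4 overlaps CLP1, NR4A1 overlaps NR4A1AS and AL163636.3 overlaps AL163636.2. Of the 10 that rose furthest, ATP6V0D2 overlaps AC023194.1 and AC023194.2 on the same strand, SEMA3E overlaps AC079799.2 and ASB2 overlaps MIR4506, with the same uncertainty. ATP6V0D2, SEMA3E, ASB2, SP140, KMO, RCAN2 and TTC39A also overlap opposite-strand genes, among them PSKH2, SP110 and OPN3. The libraries were stranded but the strand setting of the counting was not given in the sources used here, so those values carry the same doubt.

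The series title ties the drug to transcription of CD44 and TCF7L2 that runs through the kinase GSK3b, so the transcripts of these genes and of the drug's targets were compared by name. CD44, the hyaluronan receptor used as a glioma stem cell marker (ENSG00000026508, GRCh38 chromosome 11, 35138870 to 35232402), fell from 1342 ± 15.4 to 479.8 ± 14.8 CPM (SD, n = 2). Its log2 fold change was -1.48 ± 0.03 (SE, edgeR adjusted p = 7.58e-28). TCF7L2, a transcription factor of the Wnt pathway (ENSG00000148737, chromosome 10, 112950250 to 113167678), fell from 14.3 ± 0.14 to 6.82 ± 0.419 CPM, a log2 fold change of -1.06 ± 0.10 (edgeR adjusted p = 1.18e-10). GSK3B, the kinase that marks beta-catenin for degradation (ENSG00000082701, chromosome 3, 119821323 to 120094417), rose slightly, from 43.7 ± 0.0247 to 50.8 ± 0.948 CPM (0.22 ± 0.05, edgeR adjusted p = 2.27e-04). The study may have picked CD44 and TCF7L2 from these libraries, so their fall is not independent evidence of the direction. The transcripts of CDK4 and CDK6 both rose. CDK4 (ENSG00000135446, chromosome 12, 57747727 to 57756013) went from 118.7 ± 6.34 to 261.5 ± 5.28 CPM (1.14 ± 0.04, edgeR adjusted p = 1.43e-22). CDK6 (ENSG00000105810, chromosome 7, 92604921 to 92836594) went from 8.81 ± 0.464 to 14.8 ± 0.384 CPM (0.74 ± 0.10, edgeR adjusted p = 5.74e-08). All 5 genes overlap annotated genes on the opposite strand (CD44-AS1 for CD44, AL158212.2 for TCF7L2, AC092910.1 and AC092910.2 for GSK3B, TSPAN31 and MARCHF9 for CDK4, and CDK6-AS1 for CDK6), so the doubt about the strand setting covers them too. Each of the 5 except GSK3B also overlaps another annotated gene on its own strand.

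**Figure D1:**
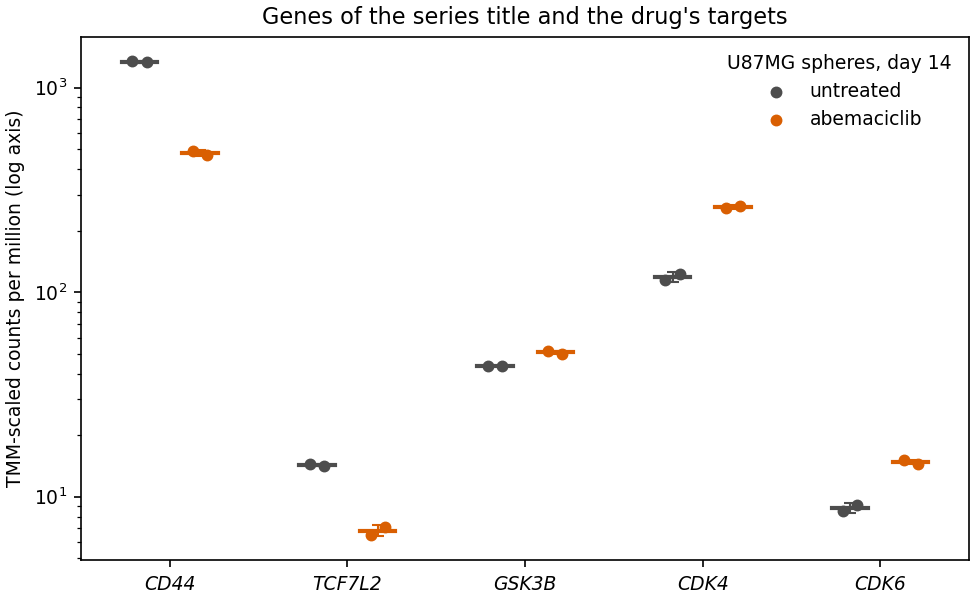
TMM-scaled CPM on a log axis for CD44, TCF7L2, GSK3B, CDK4 and CDK6 in untreated and abemaciclib-treated U87MG spheres at day 14. Points are the 2 libraries of a group, the wide line is their mean and the error bar 1 SD. CD44 and TCF7L2 lie lower after the drug (1342 to 479.8 and 14.3 to 6.82 CPM) and GSK3B, CDK4 and CDK6 higher.

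To ask which processes the changed genes belong to, 36 gene lists fixed before the data were examined were tested together with camera, which compares a list's genes with all other genes. With its preset correlation between genes, 20 lists passed an adjusted p of 0.05, 6 of them higher and 14 lower after abemaciclib. With a correlation estimated from these 4 libraries no list passed (0 of 36, smallest adjusted p = 0.202), and 7 lists had an unadjusted p under 0.05. That setting also tests each list on 2 degrees of freedom. A simulated list with every gene shifted had a camera p of 0.0126 there, so failing at it does not show that a list was unchanged. Fry, which tests a list without comparing it with other genes, called 33. Changes of a list's members are given below as counts from the edgeR test over all genes. Adjusted over the list alone, the number of changed members was the same in 32 lists and 1 higher in the other 4, which are named.

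**Figure D2:**
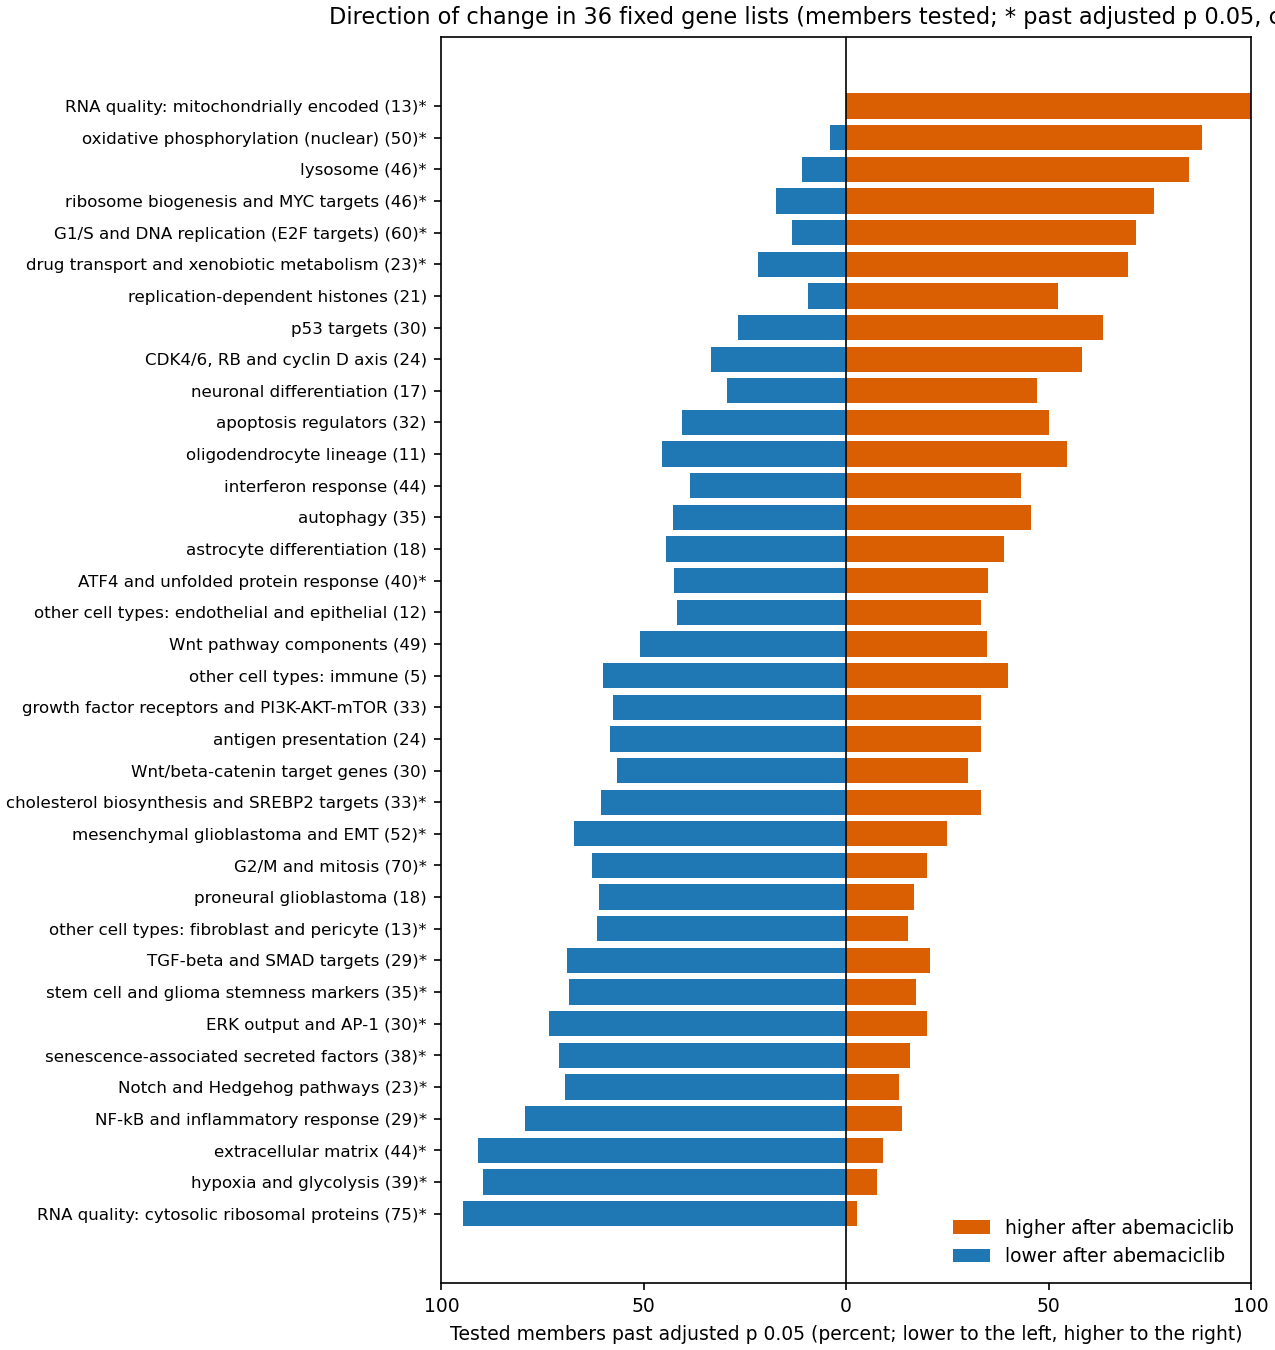
Percent of the tested members of each of 36 gene lists that were higher (right) or lower (left) after abemaciclib at an edgeR adjusted p under 0.05, with the number of members tested in brackets. An asterisk marks the 20 lists past an adjusted p of 0.05 in camera with its preset correlation. The mitochondrially encoded genes lie wholly to the right (13 of 13 higher) and the ribosomal proteins almost wholly to the left (71 of 75 lower).

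Genes of the cell cycle moved in opposite directions by phase. Of 60 tested genes of G1/S and DNA replication, 43 were higher, 8 lower and 9 not past the threshold (52 changed when adjusted over the list alone, 51 over all genes), with a median log2 fold change of 0.71 (camera adjusted p = 4.25e-06, and adjusted p = 0.421 with an estimated correlation). They included FEN1, which trims Okazaki fragments (1.80 ± 0.04), and the replicative helicase subunits MCM4 (1.46 ± 0.04), MCM5 (1.52 ± 0.04) and MCM2 (1.42 ± 0.04). RRM2, a subunit of ribonucleotide reductase, fell (-1.18 ± 0.07). Of 70 genes of G2/M and mitosis, 14 were higher, 44 lower and 12 not past the threshold, with a median of -0.59 (camera adjusted p = 9.45e-03, and adjusted p = 0.515 with an estimated correlation). HMGB2 (-1.88 ± 0.06), the condensin subunit NCAPD2 (-1.38 ± 0.05), the mitotic kinesin KIF20A (-2.49 ± 0.09) and NUSAP1 (-1.77 ± 0.07) fell, while the kinase MELK rose (1.34 ± 0.08). MKI67, the proliferation marker, chosen after its values were seen, went from 48.7 to 12.1 CPM (-2.04 ± 0.13).

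Around the drug's targets, 14 of 24 genes of the CDK4/6, RB and cyclin D axis were higher, 8 lower and 2 not past the threshold, and the list did not pass (camera adjusted p = 0.862). CCND1, the cyclin partner of CDK4 and CDK6, rose by 1.66 ± 0.03. The CDK inhibitors CDKN1A (-1.52 ± 0.04), CDKN1B (-1.80 ± 0.06) and CDKN1C fell. RB1, chosen after its values were seen, had a log2 fold change of -0.02 ± 0.12 (edgeR adjusted p = 0.913). Among 30 p53 targets 19 were higher, 8 lower and 3 not past the threshold (camera adjusted p = 0.185), with TP53I3 (1.89 ± 0.08), ZMAT3 (1.10 ± 0.05) and SESN2 (1.09 ± 0.05) up and CDKN1A and TNFRSF10B (-0.57 ± 0.03) down. Of 21 tested replication-dependent histone genes, whose transcripts mostly lack poly-A tails, 11 were higher, 2 lower and 8 not past the threshold (camera adjusted p = 0.236). H2BC12 (2.04 ± 0.09) and H2AC6 (1.11 ± 0.07) were among those that rose, and H1-2 fell (-1.35 ± 0.12). Of 32 apoptosis regulators 16 were higher, 13 lower and 3 not past the threshold (camera adjusted p = 0.862). The survival genes CFLAR (-1.32 ± 0.04) and MCL1 (-0.93 ± 0.03) fell. Of the death promoters, PMAIP1 (1.54 ± 0.07) and BAD (0.91 ± 0.05) rose and BMF fell (-1.88 ± 0.10).

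Stem cell markers were lower more often than higher. Of 35 tested stemness genes 6 were higher, 24 lower and 5 not past the threshold, with a median log2 fold change of -0.77 (camera adjusted p = 0.0152, and adjusted p = 0.499 with an estimated correlation). CD44, the differentiation inhibitor ID1 (-3.01 ± 0.09) and the Notch target HES1 (-3.43 ± 0.11) fell, while ENG (1.07 ± 0.03) and PROCR (1.04 ± 0.04) rose. The list holds CD44, which the study named and may have picked from these libraries, so it is not fully independent evidence, and 14 of its tested members are also in other lists. SOX2, chosen after its values were seen, was close to the floor at 3 counts untreated and 23 after the drug. Of 18 proneural genes 3 were higher, 11 lower and 4 not past the threshold (camera adjusted p = 0.185), with STMN1 (-1.50 ± 0.04), PDGFRA (-1.28 ± 0.05) and MAPT (-3.14 ± 0.16) down and TUBB3 up (1.55 ± 0.04).

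Mesenchymal genes also fell as a list, with 13 of 52 higher, 35 lower and 4 not past the threshold and a median of -0.68 (camera adjusted p = 5.29e-07, and adjusted p = 0.202 with an estimated correlation). TGFBI (-2.48 ± 0.03), the matrix proteins TNC (-2.34 ± 0.03) and FN1 (-1.85 ± 0.03) fell, and ANXA1 (1.70 ± 0.03) and the integrin ITGA3 (1.58 ± 0.03) rose. CD44 is a member of this list too. Markers of differentiated neural cells gave no called list. Of 18 astrocyte genes 7 were higher and 8 lower (camera adjusted p = 0.236), with CRYAB (2.15 ± 0.12) and CLU (0.99 ± 0.03) up and GJA1 (-1.59 ± 0.03) and ALDOC (-3.38 ± 0.04) down. Of 17 neuronal genes 8 were higher and 5 lower (0.293), among them GAP43 (2.93 ± 0.09) and MAP2 (2.98 ± 0.11) up and ENO2 (-2.12 ± 0.04) down. Of 11 oligodendrocyte genes 6 were higher and 5 lower (0.854), with CNP (0.83 ± 0.03) and CLDN11 (2.22 ± 0.15) up and ENPP2 (-1.22 ± 0.03) down.

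Wnt pathway genes moved both ways. Of 30 tested beta-catenin target genes 9 were higher, 17 lower and 4 not past the threshold (camera adjusted p = 0.185, not past 0.05). VEGFA (-2.97 ± 0.03) and CD44 fell, while the receptor EPHB2 (2.32 ± 0.04), CCND1 and TCF7, a transcription factor of the same family as TCF7L2 (2.72 ± 0.05), rose. The list contains TCF7L2 and CD44, which the study named. Of 49 pathway components 17 were higher, 25 lower and 7 not past the threshold (camera adjusted p = 0.0735), with the kinase CSNK1E (-2.06 ± 0.03), the ligand WNT5A (-1.35 ± 0.03) and the corepressor TLE2 (-5.04 ± 0.15) down and WNT5B up (1.24 ± 0.06). This list was called lower when low-count genes were kept (adjusted p = 0.0228, range over 11 alternatives 0.0228 to 0.195). Its median of -0.11 turned to 0.034 with the GC and length correction, chosen after seeing the data, and was -0.058 with scaling by library size, -0.19 with low-count genes kept and -0.205 without abemaciclib replicate 1. The transcript of beta-catenin, CTNNB1, chosen after its values were seen, rose slightly from 194.4 to 230.5 CPM (0.25 ± 0.03).

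Genes of hypoxia and glycolysis fell together, with 35 of 39 lower, 3 higher and 1 not past the threshold and a median log2 fold change of -1.39 (camera adjusted p = 2.51e-32, and adjusted p = 0.342 with an estimated correlation). The angiogenic factor VEGFA, the lactate transporter SLC16A3 (-2.52 ± 0.03), the glycolytic ALDOC and the mitophagy receptor BNIP3 (-3.20 ± 0.04) fell, and hexokinase HK1 rose (0.88 ± 0.03). CA9, a carbonic anhydrase induced by hypoxia, chosen after its values were seen, went from 563.7 to 11.9 CPM (-5.56 ± 0.14).

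Extracellular matrix genes fell almost throughout, with 40 of 44 lower and 4 higher and a median of -1.44 (camera adjusted p = 2.34e-29, and adjusted p = 0.202 with an estimated correlation). The proteoglycan DCN (-2.79 ± 0.04) and the collagens COL6A3 (-2.47 ± 0.03) and COL4A2 (-4.43 ± 0.06) fell, and the crosslinking enzyme LOXL1 rose (0.69 ± 0.03). Fibroblast and pericyte markers moved in the same direction, with 8 of 13 lower, 2 higher and 3 not past the threshold (camera adjusted p = 4.81e-12, and adjusted p = 0.232 with an estimated correlation), and 5 of the 13 are also matrix genes of the list above. PDGFRB (-2.16 ± 0.03) and NOTCH3 (-2.08 ± 0.03) fell and the channel subunit ABCC9 rose (1.27 ± 0.09). TGF-beta and SMAD genes were lower in 20 of 29, higher in 6 and not past the threshold in 3 (27 changed when adjusted over the list alone, 26 over all genes), with a median of -1.17 (camera adjusted p = 6.5e-11, and adjusted p = 0.202 with an estimated correlation). LTBP1 (-2.27 ± 0.03), LTBP4 (-2.28 ± 0.04) and PMEPA1 (-2.21 ± 0.06) fell, and the receptor TGFBR2 rose (1.09 ± 0.03).

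Secreted and signalling genes followed. Of 38 senescence-associated secreted factors 27 were lower, 6 higher and 5 not past the threshold (34 changed when adjusted over the list alone, 33 over all genes), with a median of -1.47 (camera adjusted p = 1.86e-21, and adjusted p = 0.232 with an estimated correlation). STC1 (-3.88 ± 0.04), IGFBP4 (-3.68 ± 0.04) and the chemokine CXCL8 (-3.09 ± 0.04) fell, and the protease PLAU rose (1.53 ± 0.03). NF-kB and inflammatory genes were lower in 23 of 29, higher in 4 and not past the threshold in 2 (28 changed when adjusted over the list alone, 27 over all genes), with a median of -1.26 (camera adjusted p = 6.13e-13, and adjusted p = 0.342 with an estimated correlation). CCL20 (-5.62 ± 0.07), the inhibitor NFKBIA (-1.35 ± 0.03) and NFKB2 (-1.26 ± 0.04) fell, and complement C3 rose (0.58 ± 0.03). Genes of ERK output and AP-1 were lower in 22 of 30, higher in 6 and not past the threshold in 2, with a median of -0.72 (camera adjusted p = 3.31e-11, and adjusted p = 0.202 with an estimated correlation). IER3 (-3.45 ± 0.03), PHLDA1 (-2.18 ± 0.03) and the transcription factor ETV4 (-4.44 ± 0.08) fell, and CCND1 rose. Notch and Hedgehog genes were lower in 16 of 23, higher in 3 and not past the threshold in 4, with a median of -0.80 (camera adjusted p = 5.06e-04, and adjusted p = 0.413 with an estimated correlation). NOTCH3, HES1 and the ligand JAG1 (-1.73 ± 0.06) fell and SUFU, which restrains Hedgehog signalling, rose (0.45 ± 0.05).

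Lysosomal genes rose together, with 39 of 46 higher, 5 lower and 2 not past the threshold and a median of 1.07 (camera adjusted p = 2.07e-31, and adjusted p = 0.202 with an estimated correlation). The lysosomal glycoprotein GPNMB (3.80 ± 0.04), the ceramidase ASAH1 (2.98 ± 0.04) and the protease CTSK (2.63 ± 0.03) rose, and GUSB fell (-1.20 ± 0.05). Autophagy genes went both ways, with 16 of 35 higher, 15 lower and 4 not past the threshold (camera adjusted p = 0.511). MAP1LC3B (1.01 ± 0.03) and RRAGD (2.44 ± 0.09) rose, and BNIP3 and BNIP3L (-1.64 ± 0.04) fell. Drug transport and xenobiotic genes were higher in 16 of 23, lower in 5 and not past the threshold in 2, with a median of 0.68 (camera adjusted p = 6.55e-04, and adjusted p = 0.232 with an estimated correlation). HMOX1, the haem oxygenase (2.83 ± 0.04), AKR1B1 (1.24 ± 0.03) and the thioredoxin reductase TXNRD1 (0.86 ± 0.04) rose and AKR1C3 fell (-0.61 ± 0.07).

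Transcripts of the respiratory chain rose from both genomes. All 13 mitochondrially encoded genes, a list kept as a sign of RNA quality, were higher, with a median of 1.48 (camera adjusted p = 3.08e-19, and adjusted p = 0.342 with an estimated correlation). MT-ND5 (2.36 ± 0.03), MT-CYB (2.07 ± 0.04) and MT-CO1 (1.02 ± 0.03) were among them. Of 50 nuclear genes of oxidative phosphorylation 44 were higher, 2 lower and 4 not past the threshold, with a median of 0.47 (camera adjusted p = 2.7e-06, and adjusted p = 0.342 with an estimated correlation). The mitochondrially encoded share of the counts rose beside this list. ATP5PB (1.01 ± 0.03) and NDUFS8 (0.85 ± 0.04) rose and SDHA fell slightly (-0.18 ± 0.04). Cytosolic ribosomal protein genes, also a sign of RNA quality, were lower in 71 of 75, higher in 2 and not past the threshold in 2, with a median of -0.48 (camera adjusted p = 1.25e-12, and adjusted p = 0.499 with an estimated correlation). RPL10 fell (-1.15 ± 0.03) and RPSA rose (0.15 ± 0.03). These genes have many processed pseudogenes with which they can share reads. Ribosome biogenesis and MYC targets rose, with 35 of 46 higher, 8 lower and 3 not past the threshold and a median of 0.55 (camera adjusted p = 1.23e-04, and adjusted p = 0.232 with an estimated correlation). NME1 (1.55 ± 0.04), the RNA polymerase I subunit POLR1A (1.69 ± 0.05) and the chaperone HSPD1 (1.06 ± 0.03) rose, and lactate dehydrogenase LDHA fell (-1.39 ± 0.03).

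**Figure D3:**
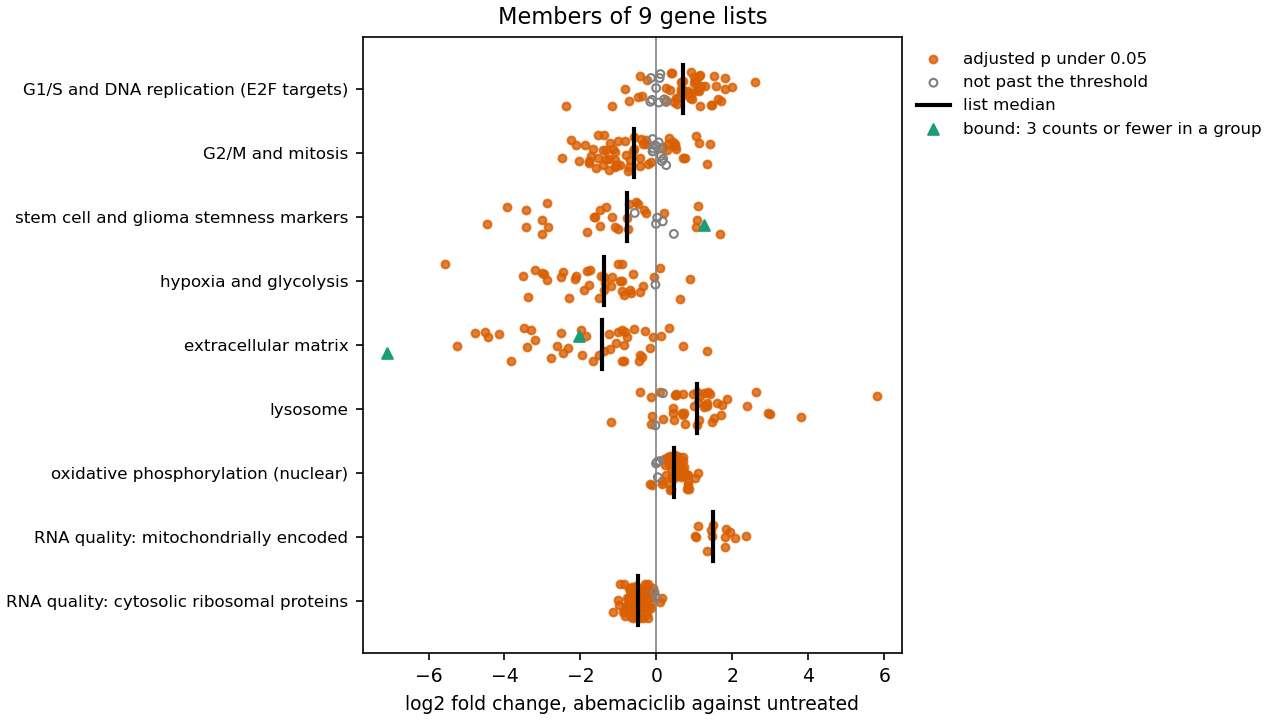
Log2 fold change (abemaciclib against untreated) of each tested member of 9 gene lists, with the list median as a black line. Filled points passed an edgeR adjusted p of 0.05, open points did not, and triangles show the bound for genes with 3 counts or fewer in a group. The medians lie at 0.71 for G1/S, -0.59 for G2/M, 1.07 for lysosome and -1.44 for extracellular matrix.

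Cholesterol synthesis genes were lower in 20 of 33, higher in 11 and not past the threshold in 2, with a median of -0.53 (camera adjusted p = 0.0226, and adjusted p = 0.499 with an estimated correlation). INSIG1 (-1.87 ± 0.03), MSMO1 (-1.45 ± 0.04) and DHCR7 (-0.90 ± 0.03) fell, while the fatty acid enzymes ACACA (1.16 ± 0.04) and SCD (0.86 ± 0.03) rose. The call ended without abemaciclib replicate 1 (adjusted p = 0.0631, range over 11 alternatives 0.00274 to 0.0631). Genes of ATF4 and the unfolded protein response were lower in 17 of 40, higher in 14 and not past the threshold in 9, with a median of -0.07 (camera adjusted p = 0.0409, and adjusted p = 0.499 with an estimated correlation). DDIT4 (-3.65 ± 0.04) and the amino acid transporter SLC7A5 (-2.06 ± 0.05) fell and the chaperone CALR rose (0.71 ± 0.03). That call ended without untreated replicate 1 (adjusted p = 0.153), without abemaciclib replicate 1 (0.0672), without abemaciclib replicate 2 (0.0576) and with scaling by library size alone (0.0699), in a range over 11 alternatives of 0.00565 to 0.153. The median was -0.028 without untreated replicate 2, -0.031 without abemaciclib replicate 2, -0.039 without abemaciclib replicate 1 and -0.016 with scaling by library size alone.

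The other lists were not called. Of 44 interferon response genes 19 were higher, 17 lower and 8 not past the threshold (camera adjusted p = 0.692). The antiviral membrane proteins IFITM3 (-2.76 ± 0.04), IFITM2 (-4.87 ± 0.08) and IFITM1 fell, while IFI6 rose (1.04 ± 0.05). Of 24 antigen presentation genes 8 were higher, 14 lower and 2 not past the threshold (0.228), with the class I genes HLA-B (-1.42 ± 0.03) and HLA-C (-1.20 ± 0.03) down and HLA-DMA up (1.28 ± 0.05). The IFITM and HLA genes are families whose reads the counting may have split. Of 33 growth factor receptor and PI3K-AKT-mTOR genes 11 were higher, 19 lower and 3 not past the threshold (0.347), with PDGFRB and AXL (-1.64 ± 0.04) down and MET (1.81 ± 0.04) and PIK3R3 (2.80 ± 0.05) up. Markers of other cell types were few. Of 12 endothelial and epithelial genes 4 were higher and 5 lower (0.369), with PECAM1 down (-3.14 ± 0.18) and EPCAM up (1.17 ± 0.25). Of 5 immune genes, 2 were higher and 3 lower (0.49), with the lysosomal protein CD68 up (1.10 ± 0.03) and CSF1R down (-1.02 ± 0.12). In 7 uncalled lists the median, the mean and the direction of the test did not share a sign. These were the astrocyte, neuronal, oligodendrocyte, immune, autophagy, apoptosis and CDK4/6 lists.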

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

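The GC and length correction, the removal of mitochondrially encoded genes and the test against a log2 fold change of 1 were chosen after seeing the data, and the other alternatives before. Across the alternatives 11233 (DESeq2) to 13789 (no filter) genes were called, and 80 of 82 counts of calls stayed within 1.5 times the value reported. The 2 that moved were counts of called lists, with an estimated correlation and with fry. For the count of all changed genes that margin reaches above the 17207 genes tested, so it is a loose one. With each library left out in turn, 12310 to 12875 genes were called, in a fit that assumes the lone library of a group to vary like the other group, and 5160 to 5497 changed at least 2-fold. The 2-fold count was lowest with at least 50 counts in 2 libraries (3622) and 3709 with the test against a log2 fold change of 1. All 25 named genes of the title, the drug's targets and the largest changes kept their direction and their call in all 425 comparisons. The genes picked for the largest changes could hardly do otherwise. The test against a log2 fold change of 1 was not among these comparisons. CD44 ranged from -1.53 to -1.43, TCF7L2 from -1.16 to -0.99, GSK3B from 0.19 to 0.27, CDK4 from 1.09 to 1.19 and CDK6 from 0.69 to 0.81. Other scalings moved the median of all genes by at most 0.0538. That shift is too small to test whether an error of scale could account for the small rise of GSK3B (0.22). The number of lists called rose from 20 to 33 with fry, which makes no comparison with other genes. It fell to 0 with an estimated correlation. That setting replaces the preset 0.01 by values estimated from 4 libraries and also tests each list on the 2 residual degrees of freedom. Most called lists had an estimated correlation above the preset. That of ERK output and AP-1 was below it (-0.0306), and its camera p still went from 8.28e-12 to 0.0162. The simulated shifted list, with genes drawn independently, went from 9.14e-57 to 0.0126. The fall to 0 therefore cannot be put down to correlation between genes alone. With 2 degrees of freedom a small p is hard to reach, so failing at this setting does not show that a list was unchanged. The lists were also tested under 11 other alternatives (3 scalings, no filter, the replicate block, the GC and length correction, mitochondrially encoded genes left out, which leaves no such list to test, and each of the 4 libraries left out), but not with the stricter filter, the other gene tests or unrounded counts. Under those run, 18 of the 20 called lists kept their call, and 18 to 20 were called with a library left out. The exceptions were ATF4 and the unfolded protein response and cholesterol synthesis, while Wnt pathway components gained a call without the filter. Their values stand with those lists in the results, and the cause was not tested. Over all tested genes together the replicate numbers showed no pairing of the libraries (correlation of same-number deviations -0.0002). That single value would not show pairing confined to some genes. With the replicate number as a block 13108 genes were called, 13060 of them also called without it, and the same 20 lists, which changed no list call. Low counts limit the genes with 3 counts or fewer in a group to bounds or wide intervals. The simulation recovered 76% of 1.5-fold changes with few genes changed. That share does not carry over to data in which 77.3% of the tested genes were called.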

Other observations

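Gene families grouped by the root of their symbol after the data were examined, 229 with at least 8 tested members, gave 9 with a camera adjusted p under 0.05 at the preset correlation and 0 with an estimated one (smallest adjusted p = 0.944). Beyond the lists already described, 8 of 10 annexin genes (ANXA) were higher and 1 lower, with a median log2 fold change of 0.64 (camera adjusted p = 0.0097). The IRF root had 9 of 10 lower and 1 higher, with a median of -0.70 (camera adjusted p = 0.0444). It was grouped by symbol alone, so it can hold genes that are not interferon regulatory factors. The CYB root, which joins cytochrome b genes of several functions, had 12 of 13 higher and 0 lower, with a median of 0.91 (camera adjusted p = 0.0012). Of 11 genes of the COMMD root, likewise grouped by symbol alone, 9 were higher and 0 lower, without passing (camera adjusted p = 0.0892). The NR root had 7 of 18 higher and 11 lower (median -0.36, camera adjusted p = 0.0216), and the ATP root, which joins several kinds of ATPase and ATP synthase genes, 44 of 73 higher, 19 lower and 10 not past the threshold (median 0.41, camera adjusted p = 1.02e-04). The other called roots were COL, RPL, RPS and MCM, which hold genes of lists in the results. All 9 calls ended with an estimated correlation (camera adjusted p = 0.944), a setting with the limit given above for the lists.

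Long noncoding RNAs also changed, 153 higher and 278 lower among 431 past the same rule as for the named genes. How many were tested is not given here, and 77.3% of all tested genes were called. The counts therefore show nothing particular to this class. MIR210HG, the host transcript of the hypoxia-induced microRNA miR-210, went from 4752 counts over the untreated libraries to 160 after the drug, a log2 fold change of -4.85 ± 0.09 (SE). DICER1-AS1 went from 17.2 to 0.509 CPM (-5.14 ± 0.18). Among those that rose were AC016831.1, from 3.90 to 71.9 CPM (4.21 ± 0.08), LINC02308 (5.17 ± 0.21) and SMIM25 (4.57 ± 0.19). By this rule AL031429.1 rose furthest, from 2 counts over the untreated libraries to 1272 after the drug, followed by AC007099.1, from 2 to 298. AC008105.3 fell furthest, from 554 counts to 4. DICER1-AS1, AL031429.1, AC007099.1 and AC008105.3 are annotated as antisense, and the strand setting of the counting was not given.

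Of the tests below, those of short transcripts, of leakage, of cells of another line and of replicate closeness were chosen after the result was seen, and the GC and length correction after seeing the data. The G1/S list was higher and the G2/M list lower. One scaling factor per library moves every gene alike, so no choice of factor makes or removes the gap of 1.2971 between the medians. With the GC and length trend removed the gap was 1.3214. A change in the mix of cycle phases stays open, since the libraries hold no measure of the cycle, and no biological explanation was tested.

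Ribosomal protein genes were lower while mitochondrial transcripts were higher. Protein-coding genes matched to them on transcript length (750 genes, median 641 nt) had a median of -0.0073 against -0.4822, which counts against a loss of short transcripts as the whole cause. The summed CPM of 1148 ribosomal protein pseudogenes changed by -345.53 while that of the genes changed by -11535.1, so reads did not move to the pseudogenes. Leakage of cytosolic RNA from damaged cells would lower nuclear transcripts alike, but the nuclear oxidative phosphorylation list lay 0.9503 above the ribosomal protein list. This counts against leakage as the whole cause of the ribosomal protein fall. It does not test leakage as a source of the mitochondrial rise, because an even loss of nuclear transcripts would leave that gap unchanged. No biological explanation was tested.

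Most tested genes changed, and the other scalings moved the median of all genes by at most 0.0538, too little to test a larger error of scale. Cells of another line with an intact 9p21 region, which U87MG lacks, would bring CDKN2A, CDKN2B and MTAP, and the highest sum of their counts in any library was 2, a test that does not reach a line that lacks 9p21 too. Replicates that are closer to each other than separate cultures would be could also give many calls. The smaller chi-square per degree of freedom was 1.954 and the coefficient of variation 2.86%, and technical replicates and separate cultures cannot be told apart, because the labels do not say which these were. The effect of the drug itself, the difference that the design names, stays open as an untested explanation.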
